A study of Mus musculus with 502 samples.

How the data were processed

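Silencers were mapped with Ss-STARR-seq, a plasmid reporter assay in which sheared genomic fragments are cloned into a vector, transfected into cells, and counted in the plasmid DNA (input) and in the RNA made from it (output). The genome was sheared into short fragments, per the labels' protocols. The labels list 502 libraries in 5 groups: 102 of 293T output RNA, 1 of 293T input DNA, 180 of K562 output RNA, 179 of LNCap output RNA and 40 of LNCap input DNA. None of these 502 libraries is a K562 input, and the reads of no library were analysed here. Every library is labelled as mouse, whereas the lines named are human and the build named is human. The lists were treated as human for that reason.

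The analysis started from the authors' 3 silencer lists, 1 per cell line, with the columns chromosome, start, end and activity, per the file headers. Reads were handled with Bowtie2 and SAMtools and the build was hg38, per the submitters' processing notes, which give no tool versions. The region caller, its thresholds and the way libraries were combined are not given in the sources used here. The activity column is a score of the authors, deposited with 1 decimal. Whether it is linear or logarithmic is not stated, so it was used only to describe and rank silencers within a list. No deposited score lies below 2. Read depth is unknown because the lists hold no counts, and no interval that needs depth is given. Positions are printed as deposited; whether starts count from 0 or 1 is not stated.

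Lines whose fields were cut or run together were left out, as were lines with an unknown chromosome, an end not above the start, or a width over 5000 bp. These filters removed 58 lines for 293T, 12 for K562 and 25 for LNCap. Lines with an infinite activity (2, 31 and 13) were kept for positions. Each chromosome's length was taken as the highest end in any list, since no human genome was used here.

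Overlap was at least 1 bp. The expected overlap was the mean of 1000 circular shifts of the other list along each chromosome, with a one-sided empirical p whose smallest possible value is 0.001. Shifts were multiples of 50 bp, a step picked after the 50 bp windows of the lists had been seen. For sharing by all 3 lists, K562 and LNCap were shifted independently. Shares carry 95% Wilson intervals and chromosome densities exact Poisson intervals; both cover counting error only. Clustering was the median gap between neighbouring silencers against 1000 uniform reshuffles (two-sided, smallest p 0.002). Regional differences were counted in 1 Mb bins with at least 20 silencers over the 3 lists, after scaling lists to equal size, where a list was over 2 times or under 0.5 times the mean of the other 2. Chance counts for these bins are means of 200 multinomial draws, which treat silencers as independent and cover counting error only. Differences between list pairs were tested over the 22 autosomes by a two-sided sign-flip permutation test with 100000 resamples (smallest p 1e-05) and Benjamini-Hochberg adjustment within each family. With 1 list per line, all p-values describe positions or chromosomes, not replicate cultures.

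Tests, alternatives and naming rules were fixed before the data were examined. Without a human annotation the rule names, per line, the 8 bins with the highest ratio, the 8 bins with most silencers in the mean of the lists, and the 3 highest finite scores per list. Chromosomes were to be named at a ratio over 1.5 or under 0.67, which only Y met; chromosomes 17, 19 and 22 were picked after their ratios were seen. The sign-flip tests, the 5 activity classes, the split at the median activity, the comparison of start offsets and the split of silencers by sharing were also chosen after seeing the data. Analyses that need a human genome or annotation (gene features, promoters, gene lists, base composition and motifs) were not run.

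The procedures were tested on simulated data. In 40 pairs of unrelated lists with the sizes and widths of K562 and LNCap, the median fold was 0.998 and 1 pair had a p under 0.05. Simulated silencers were placed uniformly and all on the 50 bp grid. The clustering, shared regional density and other start offsets of the real lists were therefore not covered. A planted K562 and LNCap sharing of 10% was recovered as an excess of 9.91%, and 2% as 1.99%. Of 60 bins of 2917 in which 293T was raised 3 times, 58 were recovered, with 3 other bins over the rule. The raised bins were drawn only from fuller bins, well above the minimum of 20 silencers. Recovery in sparser bins was therefore not covered. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.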

Results

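Genome-wide silencer activity was measured by Ss-STARR-seq in 3 human cell lines: K562, a leukaemia line with erythroid features; LNCap, an androgen-sensitive prostate cancer line; and 293T, a line derived from embryonic kidney. The 461 output RNA and 41 input DNA libraries of the series are represented by 1 silencer list per line. The lists held 125307 lines for 293T, 134171 for K562 and 137753 for LNCap, equal to the numbers of silencers in the series' design text. After removal of broken or impossible lines, 125249, 134159 and 137728 silencers were analysed. There are no replicate lists, and the read depth behind each silencer is unknown.

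The listed silencers were short in all 3 lines. Their widths were multiples of 50 bp for 91.6% of 293T, 88.7% of K562 and 91.7% of LNCap silencers. They thus follow the 50 bp windows of the lists and do not measure the length of an element. The median width was 50 bp in each list, and silencers of exactly 50 bp made up 64.5% of the 293T list, 58.7% of the K562 list and 60.6% of the LNCap list. Together the silencers covered 10.4 Mb in 293T, 12.3 Mb in K562 and 12.6 Mb in LNCap. The widest silencers measured 1030, 1259 and 1258 bp. Silencers often lay 1 window apart: a gap of exactly 50 bp separated 7.16% of neighbours in 293T, 6.77% in K562 and 7.36% in LNCap. Merging silencers within 500 bp left 107920, 116276 and 117889 regions.

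The authors' activity score had a median of 2.3 in 293T and 2.2 in K562 and LNCap. The upper quartile was 2.6, 2.5 and 2.6, and the highest finite scores were 10.4, 11.8 and 15.7. In 293T the highest scores belonged to silencers on chromosome 5 (142345050 to 142345101, score 10.4), chromosome 17 (44442069 to 44442119, score 10.4) and chromosome 4 (104255800 to 104255871, score 10.2). In K562 they lay on chromosome 8 (105691136 to 105691200, score 11.8), chromosome 1 (26152801 to 26152851, score 10.3) and chromosome 2 (32343641 to 32343691, score 10.1). In LNCap they lay on chromosome 4 (112705412 to 112705462, score 15.7), chromosome 9 (5746201 to 5746251, score 11.8) and chromosome 4 (46633313 to 46633363, score 11.6). Of these silencers, the K562 silencer on chromosome 8 overlapped a silencer of another list, LNCap; the others overlapped none. All positions are on hg38.

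The study asked how far silencers are specific to a cell line. Most silencers were found in 1 list. Without replicate lists, a silencer missed in another line cannot be told apart from one that is absent there, so this share does not measure specificity. K562 and LNCap shared the most: 21078 of 134159 K562 silencers (15.7%, 95% Wilson interval 15.5 to 15.9) overlapped a LNCap silencer, against 0.801% after circular shifts, a 19.6-fold excess. In the other direction, 15.4% of LNCap silencers overlapped a K562 silencer. The 293T list shared less with both. Of 125249 silencers in 293T, 4130 (3.30%, interval 3.20 to 3.40) overlapped K562, a 4.54-fold excess, and 4487 (3.58%, interval 3.48 to 3.69) overlapped LNCap, a 4.84-fold excess. The K562 and LNCap excess ranged from 9.93-fold with silencers set to 300 bp to 34.7-fold above the median score, where the 293T values were 7.37 for K562 and 7.74 for LNCap. In the main setting each pair gave p = 0.001 (one-sided), the smallest value that the shifts can give.

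**Figure D1:**
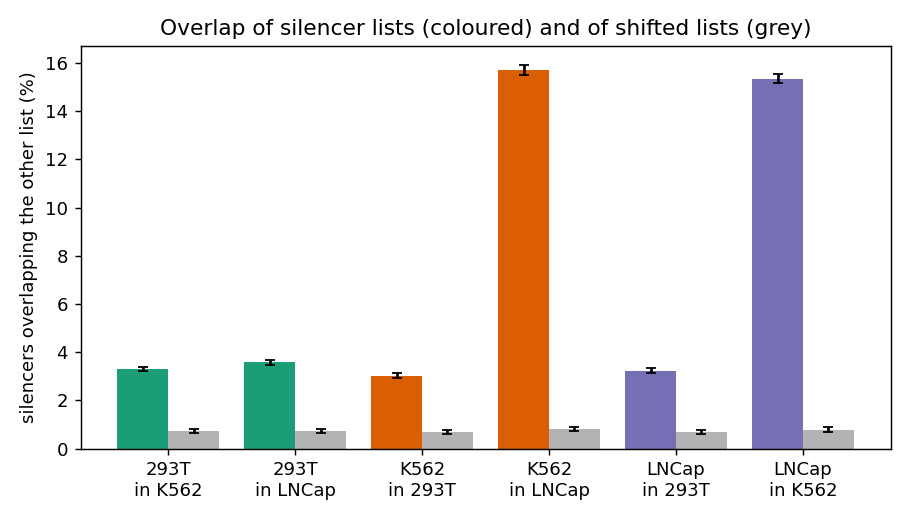
Share of each list's silencers (percent, y axis) that overlap another list (coloured bars, 95% Wilson intervals) and the mean share after circular shifts (grey bars, with the lowest and highest of 1000 shifts), for each ordered pair of lists. K562 and LNCap overlap at 15.7% and 15.4%, all pairs with 293T at 3.03% to 3.58%.

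The excess differed between pairs of lists. The fold of LNCap silencers in the K562 list was 4.01 times that in the 293T list (mean log2 difference 2.00, SD over autosomes 0.29, higher on 22 of 22 autosomes, sign-flip permutation p = 1e-05, adjusted p = 1.5e-05). For K562 silencers, the fold in the LNCap list was 4.28 times that in the 293T list (mean log2 difference 2.10, SD 0.29, 22 of 22 autosomes, permutation p = 1e-05, adjusted p = 1.5e-05). The 293T list overlapped LNCap slightly more than K562 (1.06 times, 17 of 22 autosomes, permutation p = 0.012, adjusted p = 0.012). Those 3 comparisons form 1 family.

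The 3 lists together formed 367012 merged regions. Regions held by 1 list numbered 117618 in 293T (32.0%), 110094 in K562 (30.0%) and 113224 in LNCap (30.9%). K562 and LNCap alone shared 18768 regions (5.11%), 293T and LNCap 3141 (0.856%), and 293T and K562 2802 (0.763%). All 3 lists held 1365 regions (0.372%), against 14.1 after shifting K562 and LNCap independently, a 96.6-fold excess (one-sided p = 0.001). The excess was 13.3-fold with midpoints within 500 bp, 58.6-fold with local shifts and 292-fold among silencers above the median score. That expectation ignores the sharing between K562 and LNCap. With only 293T shifted, K562 silencers shared with LNCap overlapped 293T 6.18 times more often than shifted lists did, and other K562 silencers 4.12 times. The shared K562 silencers had a median width of 100 bp against 50 bp for the others, and wider silencers meet the rule of 1 bp more often. That width also enters the shifted share (0.829% for shared, 0.641% for others), by which the observed share (5.12% and 2.64%) is divided. K562 silencers above the median score overlapped both LNCap and 293T more often than the rest. The contrast of 6.18 with 4.12 was neither adjusted for score nor tested.

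Sharing rose with the activity score. Of K562 silencers scoring 2 to 2.1, 12.4% (95% Wilson interval 12.1 to 12.7) overlapped LNCap, rising to 27.1% (interval 25.3 to 29.1) at finite scores of 4 and above. Silencers with an infinite score, left out of these classes, overlapped in 2 of 31 cases for K562 in LNCap, 1 of 13 for LNCap in K562, 0 of 31 for K562 in 293T and 1 of 13 for LNCap in 293T. LNCap silencers overlapping K562 rose from 10.6% to 29.8% over the same classes. The smaller overlap with 293T rose likewise, from 2.43% to 4.78% for K562 silencers and from 2.39% to 5.50% for LNCap silencers. Silencers above the list's median score overlapped more than the rest in all 6 ordered pairs, by 1.34 to 1.72 times (higher on at least 21 of 22 autosomes, sign-flip permutation p = 1e-05 and adjusted p = 1e-05 in each). The rise was not detectably different between K562 in LNCap and K562 in 293T (mean log2 difference 0.03, SD 0.26, permutation p = 0.54). For LNCap silencers it was 1.72 times in K562 and 1.56 times in 293T, a difference that was not tested.

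Among autosomes, chromosome 19 was the densest in each list and, over its full length, chromosome 21 the sparsest. Per Mb of occupied 100 kb bins, chromosome 6 was sparser than chromosome 21 in K562 (39.7 against 41.4). Chromosome 19 held 58.2 silencers per Mb in 293T (exact Poisson interval 56.2 to 60.1), 87.7 in K562 (85.3 to 90.1) and 93.7 in LNCap (91.3 to 96.3). The 293T list thus placed a smaller share on chromosome 19, at 0.696 times the mean share of the other 2 lists, and likewise on chromosomes 22 (0.701 times) and 17 (0.770 times). These ratios lie inside the range of 0.67 to 1.5 set for naming a chromosome. Chromosome Y was outside it, with a ratio of 2.13 in K562 and 0.491 in 293T, on 14 and 5 silencers; LNCap had 8. Between 56 and 57 Mb lay 13 of the 14 in K562, 4 of the 5 in 293T and 7 of the 8 in LNCap. The remaining 1 of each list lay at 11 Mb. The placement was thus common to the 3 lists. Occupied 100 kb bins of chromosome Y covered 0.2 Mb. How uniquely reads map there was not examined, so the ratios on Y cannot be read as a property of a line.

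**Figure D2:**
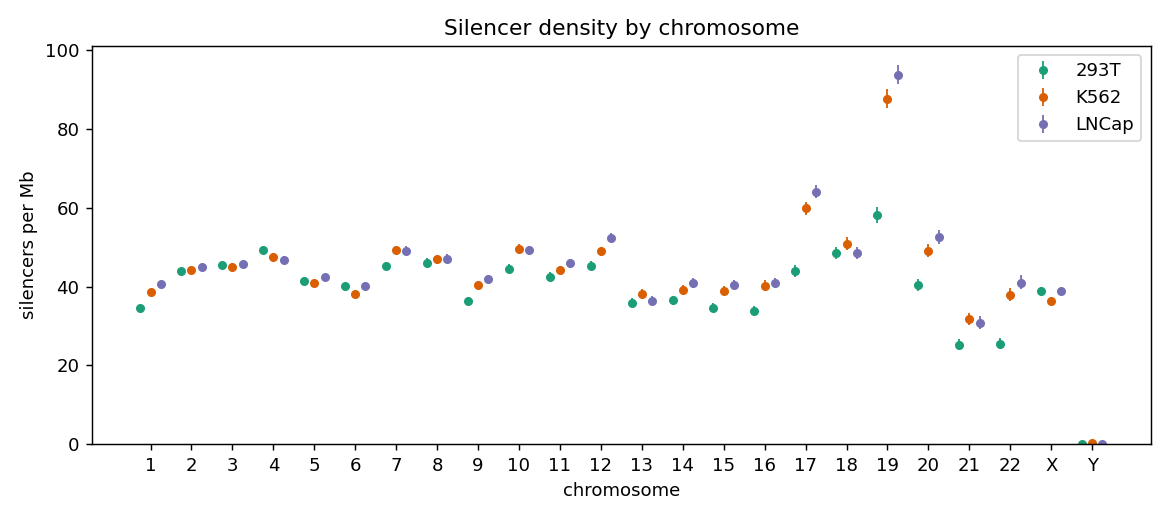
Silencers per Mb (y axis) on each chromosome (x axis) in 293T, K562 and LNCap, with exact Poisson intervals that cover counting error only. Chromosome 19 is the densest, at 58.2, 87.7 and 93.7 per Mb.

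In 1 Mb bins, the K562 and LNCap counts followed each other more closely than either followed 293T. The Spearman correlation over 2856 bins, which are not independent replicates, was 0.81 for K562 and LNCap, 0.63 for 293T and K562, and 0.55 for 293T and LNCap. Each bin with at least 20 silencers held some from each line. 293T exceeded 2 times the mean of the other lists in 55 bins, against 2.09 by chance draws, and was under 0.5 times in 50, against 6.73. K562 did so in 6 and 10 bins (1.76 and 5.25 by chance), and LNCap in 4 and 41 (1.93 and 5.36 by chance). These counts overlap, because each ratio is taken against the other 2 lists. The bin on chromosome 4 from 104 to 105 Mb counted as high for 293T (3.01 times) and low for K562 (0.460 times). That on chromosome 22 from 10 to 11 Mb counted as high for K562 (2.41 times) and low for 293T (0.329 times). The draws treat silencers as independent and cover counting error only. Whether copy number differences between the lines, or an input common to K562 and LNCap, enter these counts was not tested. How uniquely reads map was not examined either, for these counts or for the bins named below.

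The bins with the highest 293T ratio lay on chromosome 6 from 128 to 129 Mb (3.09 times; 30 silencers in 293T, 12 in K562 and 9 in LNCap) and chromosome 4 from 104 to 105 Mb (3.01 times; 72, 24 and 28). The next were on chromosome X from 93 to 94 Mb, 76 to 77 Mb and 66 to 67 Mb (2.78, 2.71 and 2.57 times), chromosome 20 from 26 to 27 Mb (2.77 times), chromosome 13 from 70 to 71 Mb (2.72 times) and chromosome 6 from 141 to 142 Mb (2.67 times). The highest K562 ratios mostly rested on few silencers, so their counting error is large. They lay on chromosome 12 from 35 to 36 Mb (3.61 times, 13 silencers against 4 in 293T and 3 in LNCap) and chromosome 22 from 10 to 11 Mb (2.41 times, 29 against 7 and 17). Next were chromosome Y from 56 to 57 Mb (2.34 times, 13 against 4 and 7) and chromosome 7 from 60 to 61 Mb (2.27 times, 16 against 5 and 9). Chromosome 9 held the bins at 65 to 66 Mb (2.10 times), 79 to 80 Mb (2.08 times) and 43 to 44 Mb (1.97 times), and chromosome 21 that at 7 to 8 Mb (2.00 times). For LNCap they lay on chromosome 12 from 133 to 134 Mb (2.56 times) and 106 to 107 Mb (2.05 times), chromosome 17 from 80 to 81 Mb (2.08 times), chromosome 15 from 66 to 67 Mb (2.00 times) and 69 to 70 Mb (1.99 times), chromosome 1 from 113 to 114 Mb (1.99 times), chromosome 22 from 21 to 22 Mb (1.97 times) and chromosome 8 from 141 to 142 Mb (1.97 times).

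After scaling the lists to equal size, the bin with most silencers in their mean was on chromosome 10 from 38 to 39 Mb, with 104 in 293T, 162 in K562 and 125 in LNCap. The other 7 of the 8 fullest bins were on chromosome 19. The fullest of them, from 4 to 5 Mb, held 77, 135 and 179 silencers, and that from 47 to 48 Mb held 86, 152 and 138. The rest started at 17, 6, 14, 12 and 45 Mb.

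Silencers of a list lay closer together than reshuffled ones. The median gap was 12850 bp in 293T, 11477 bp in K562 and 11000 bp in LNCap, which is 0.781, 0.751 and 0.740 times that of uniform reshuffles (two-sided p = 0.002 in each, the smallest the reshuffles can give). After merging within 500 bp the ratios were 0.968, 0.921 and 0.928, each with p = 0.002. Between lists, pairs of midpoints 100 to 300 bp apart were 6.05 times as dense for K562 and LNCap as pairs 200 to 500 kb apart, and 2.48 and 2.62 times for 293T with K562 and with LNCap.

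**Figure D3:**
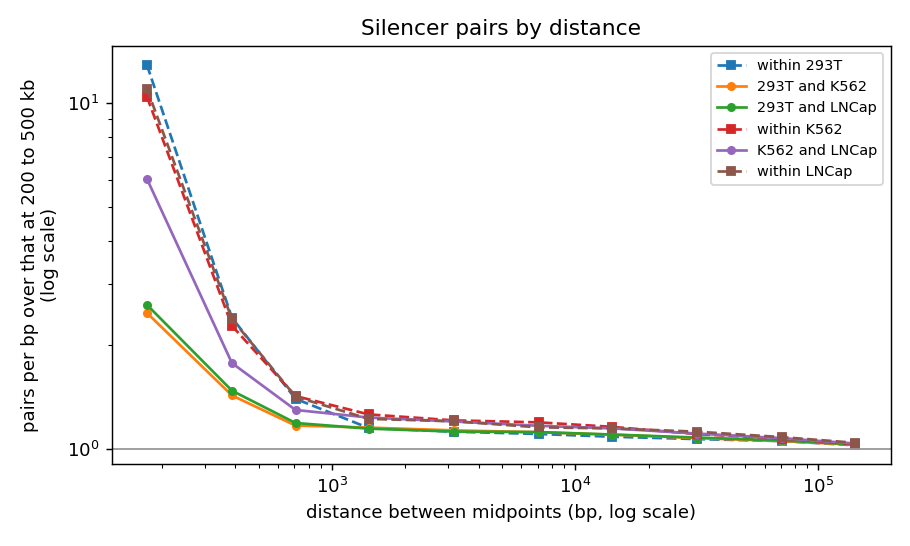
Pairs of silencer midpoints per bp of distance, relative to pairs 200 to 500 kb apart (y axis, log scale), by distance in bp (x axis, log scale), within each list (dashed) and between lists (solid). At 100 to 300 bp the value is 6.05 for K562 and LNCap and 2.48 and 2.62 for the pairs with 293T.

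The lists carry traces of how their windows were laid. Starts at 1 modulo 50 made up 53.6% of 293T, 43.3% of K562 and 43.8% of LNCap silencers. Among silencers that started at neither 0 nor 1 modulo 50, here called off-grid, overlapping silencers of K562 and LNCap had the same start offset in 2145 of 7302 pairs (29.4%, Wilson interval 28.3 to 30.4). The share was 6.00% (interval 4.70 to 7.63) of 1017 pairs of 293T and K562, and 4.29% (interval 3.30 to 5.55) of 1260 pairs of 293T and LNCap. At gaps of 5000 to 20000 bp, all 3 pairs of lists lay at 3.04% to 3.05%.

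**Figure D4:**
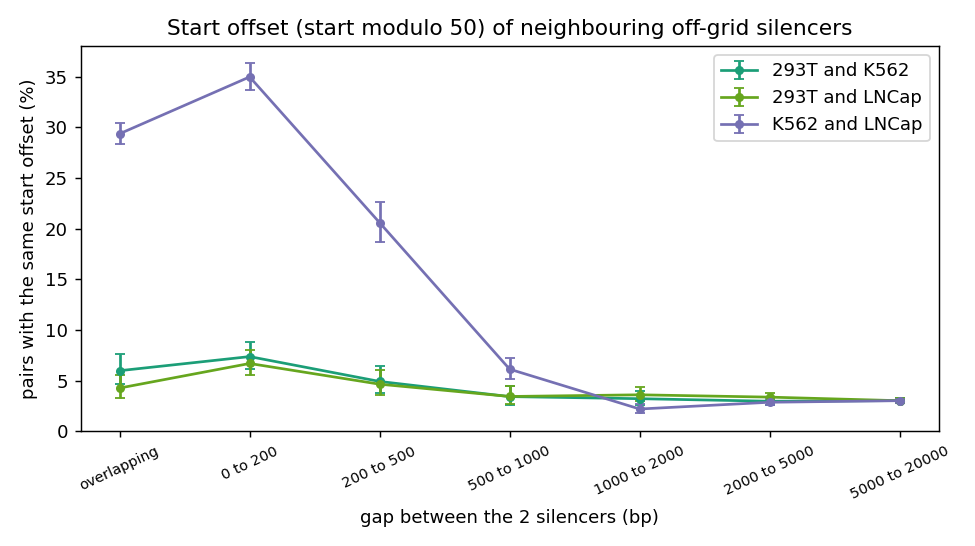
Share of neighbouring silencers, both off the common grid, with the same start offset (percent, y axis, 95% Wilson intervals) by the gap between them in bp (x axis), for each pair of lists. Overlapping silencers of K562 and LNCap share their offset in 29.4% of pairs, those of 293T with K562 in 6.00%.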

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

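The sign-flip tests, the comparison of start offsets, the restriction to the common grid, the chromosome ratio above the median score and the choice of chromosomes 17, 19 and 22 were made after the data had been seen. Overlap differed between pairs of lists by a test of the difference itself over autosomes, with 1 list per line. Relative to shifts, LNCap silencers met the K562 list 4.01 times as often as the 293T list. On the same measure, K562 silencers met the LNCap list 4.28 times as often as the 293T list. The fold of 293T silencers in the LNCap list was 1.06 times that in the K562 list.

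For the closer overlap of K562 and LNCap, the tables argue against 3 technical explanations as the whole cause, each of which needed the K562 and LNCap fold to be at most 1.2 times the higher 293T fold. It was 3.78 times with local shifts, which keep regional density, 5.81 times among silencers on the common window grid, and 4.49 times among silencers above the median score. That last split removes only scores up to 2.3 in 293T and 2.2 in K562 and LNCap, so calls slightly above the cutoff remain in it. A candidate explanation that stays open is that K562 and LNCap were called over common candidate regions or with a common input, since overlapping off-grid pairs shared their start offset 4.90 times as often as the higher 293T pair; that value was chosen after the lists were seen, and like fragments in both lines might give it too. A biological difference between the lines stays open and untested, and without read counts a simulation of a shared input was not run.

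For the lower 293T share on chromosomes 17, 19 and 22, 1 explanation was calls near the score cutoff. It needed a ratio over 0.9 on chromosome 19 above the median score, and the ratio was 0.659. This argues against calls at or below the median score as the whole cause on chromosome 19. The medians lie close to the lowest score of 2, so calls slightly above the cutoff are not covered. Chromosome 17 moved from 0.770 to 0.752, and chromosome 22 the other way, from 0.701 to 0.732. A few regions as the whole cause needed at most 50% of bins to have a 293T ratio under 1, and 82.5% of 171 did (Wilson interval 76.1 to 87.4, which includes the bound of 80% set beforehand against it). The median bin, a test added after the result was seen, had a ratio of 0.717 (95% interval 0.681 to 0.776), against 1.05 (1.03 to 1.07) in the bins of other chromosomes. These intervals treat neighbouring bins as independent. The chromosomes were picked for low ratios, so the contrast with others was largely fixed beforehand. Of the other autosomes, 20 (0.861), 21 (0.874) and 16 (0.903) had the next lowest 293T ratios. Base composition could not be examined, and the difference between lines was not tested as a biological one. The labelled input libraries also differed in number, with 1 for 293T, 40 for LNCap and no K562 input among the 502. The lists do not name the input that each was called against. A common input or common candidate regions for K562 and LNCap thus stay open here too, and were not tested for this pattern.

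For the short gaps within lists, most of the closeness lay within 500 bp: after merging at that distance the highest ratio to reshuffled gaps was 0.968, and each list lay over 0.9. Merging removes short gaps whatever made them, so elements split by uncalled windows and separate neighbouring silencers cannot be told apart. Off-grid neighbours up to 200 bp apart shared their start offset in 91.5% (293T), 90.2% (K562) and 90.1% (LNCap) of pairs, against 0.559% to 4.10% beyond 1000 bp; windows laid over 1 parent region give this whether that region holds 1 element or several. Stretches without silencers as the whole cause needed ratios over 0.9 inside occupied bins, and these were 0.806 in 293T, 0.778 in K562 and 0.767 in LNCap; the first is above the bound of 0.8 set beforehand against it. No biological explanation was tested.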

How the results depend on the processing

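The shifts of any number of bases, the common grid (with circular or local shifts) and the chromosome ratios above the median score were chosen after seeing the data. All 35 alternative values of pairwise overlap and three-way sharing stayed above 1, with p at its smallest possible value of 0.001, so p shows nothing of their stability. The folds moved: from 3.17 to 7.37 for 293T in K562, 3.32 to 7.74 for 293T in LNCap, and 9.93 to 34.7 for K562 in LNCap, lowest at 300 bp and highest above the median score. The three-way fold ranged from 13.3 (midpoints within 500 bp) to 292 (above the median score). The K562 and LNCap fold over the higher 293T fold ranged from 2.99 (300 bp around the midpoint) to 5.81 (common grid) over 10 alternatives. Clustering ratios stayed under 1 in each list, with p at its smallest value of 0.002. The counts of regional bins depended on the settings, in part because smaller bins and shorter lists hold fewer silencers each. With 500 kb bins, bins over 2 times and under 0.5 times numbered 241 and 251 for 293T, 37 and 143 for K562, and 44 and 199 for LNCap, where chance draws gave 33.4 and 86.7, 31.1 and 77.0, and 32.0 and 73.5. With 2 Mb bins they numbered 7 and 8, 2 and 2, and 0 and 11 (chance 0.25 to 0.80). Above the median score they numbered 138 and 158, 22 and 88, and 43 and 111 (chance 22.8 and 61.1, 21.8 and 48.8, and 21.4 and 41.7). The K562 count over 2 times was 10 with a minimum of 10 silencers and 3 with a minimum of 40. Density relative to the genome moved when only occupied 100 kb bins counted as length: on chromosome 21 to 0.739, 0.868 and 0.822 (293T, K562, LNCap), on chromosome 22 to 0.809, 1.12 and 1.18, and on Y to 0.562, 1.47 and 0.818. On chromosome 22 the K562 and LNCap values, and on Y the K562 value, crossed 1, since unoccupied length is left out. No paired analysis was possible because each list pools its line's libraries and carries no replicate numbers; for the same reason no replicate was left out. Alternatives for gene features, promoters, gene lists, base composition and motifs were not run. Depth is unknown, so its effect on which silencers were called was not assessed.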

Other observations

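The tests in this part were chosen after the result was seen. A lower 293T share near chromosome ends was taken as a hypothesis from the bins with the lowest 293T ratios, such as chromosome 12 from 132 to 133 Mb (15 silencers in 293T, 58 in K562 and 65 in LNCap). Within 5 Mb of an end, the median log2 ratio of 293T to the other lists, relative to the rest of the same chromosome, was -0.26 (SD 0.27 over 39 ends with at least 20 silencers). It was below 0 at 31 of 39 ends (sign-flip permutation p = 3e-05, adjusted p = 6e-05 over 2 tests), but these include the ends that prompted the test. The 39 ends lay on 22 autosomes, and ends of 1 chromosome share the rest of it as baseline, so they are not independent. Without the 3 ends that hold one of the 8 lowest bins the median was -0.25 (28 of 36 below 0, permutation p = 2e-05). Without the 13 ends that hold any bin under 0.5 times it was -0.17 (18 of 26 below 0, permutation p = 0.0029). The distance to the end may stand for base composition or gene density, which were not analysed here. Whether a common input or common candidate regions of K562 and LNCap enter this contrast was not tested either.

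A higher K562 share beside long stretches without silencers was not detectable. Within 2 Mb of the 60 autosomal stretches of at least 500 kb, the median log2 ratio was 0.088 over 20 chromosomes (SD 0.21, above 0 on 13, sign-flip permutation p = 0.23, adjusted p = 0.23).

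Regions with identical start and end in a pair of lists numbered 1496 for K562 and LNCap, 161 for 293T and K562, and 148 for 293T and LNCap. Across the 1496 regions, which are not independent replicates, the scores of K562 and LNCap had a Spearman correlation of 0.41. It was 0.07 across the 161 regions of 293T and K562, and 0.24 across the 148 regions of 293T and LNCap; the differences between these values were not tested.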
